A study of Litchi chinensis with 12 samples.

How the data were processed

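The study measured total RNA of the lychee cultivar 'Feizixiao' (Litchi chinensis) after inoculation with Peronophythora litchii, the oomycete that causes lychee downy blight. Leaves and fruits received either a suspension of 10000 spores per mL or sterile water as mock, and were collected after 24 h, per the labels. There were 12 libraries in 4 groups of 3, namely inoculated leaf, mock leaf, inoculated fruit and mock fruit. Each library's group came from its description label. The labels do not say whether the libraries of a group came from separate trees, so all p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, ribosomal RNA was depleted and strand-specific libraries were sequenced on an Illumina NovaSeq. The extraction protocol mentions leaves in the labels of all samples, fruits included.

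The authors deposited 3 tables with 1 column per library. The mRNA and lncRNA values were FPKM, as the deposited tables name them, calculated by the authors. The mRNA table held 36885 features, of which 35214 were numbered gene models and 1671 were genes given as new. There were 2625 lncRNA transcripts and 4682 circular RNAs, the latter given by the chromosome, start and end of their back-splice junction. The deposited circRNA values are treated here as a signal: within a library, 100% of the non-zero values were whole multiples, within 0.01, of a single step equal to the smallest non-zero value divided by 2. The deposited table calls them FPKM, but values of that form carry no length term. The smallest value then corresponds to 2 reads, and a value of 0 can hide a single read. Per the submitters' processing notes, TopHat2 2.0.12, Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq 1.18.0 were used, without a stated role for each. The genome build, the annotation and the circRNA caller were not given in the sources used here, and coordinates are printed as deposited.

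Tests used limma 3.58.1 in R 4.3.3, with a trend in the moderated variance, on log2(FPKM + 1). For circRNAs the pseudocount was 0.148, the smallest non-zero value of the table. A fit of the 4 group means used all 12 libraries. Its contrasts were inoculated against mock in leaf and in fruit, the difference between these responses, and mock fruit against mock leaf. A feature's variance is shared by the 4 groups, so groups listed at 0 lower it. For features with such groups, p-values can be too small where the compared groups vary. mRNA and lncRNA features entered with FPKM of at least 0.5 in at least 3 libraries, and circRNAs with a non-zero value in at least 3 libraries, which left 20383 mRNAs, 842 lncRNAs and 720 circRNAs. The threshold was a Benjamini-Hochberg adjusted p of 0.05, without a size threshold. Changes are differences on the log2(value + pseudocount) scale, which understates the change of low features. Values of single libraries were compared with two-sided exact permutation tests, for which 3 libraries against 3 cannot give a p below 0.1.

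Named features were the 2 with the greatest rise and the 2 with the greatest fall in each comparison, among those past the threshold whose 3 libraries did not overlap the 3 of the other group. For the difference of responses the rule required that the ranges of the responses did not overlap. The identifiers in the files are not paired with gene names, so no function is given, and the 37 gene lists that had been fixed could not be tested. An FPKM of 0 is described as listed at 0, with no fold against it. Folds of circRNAs against groups at 0 used a floor of 3 reads per library.

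The fit was tested on 20 simulated sets per table and tissue. Normal noise was drawn around the real mock means, with the moderated variances of the fit and the same spread in all 4 groups. The fit assumes this too, so the shares below need not hold where the spread differs between groups. Changes were placed only in features whose mean in mock of that tissue lay far above the entry filter. The recovered shares thus do not describe lower features, which are most of the 842 lncRNAs and 720 circRNAs tested. For mRNA, 200 features were changed, and 92% of log2 changes of 1 in leaf and 93.6% in fruit were recovered. For lncRNA with 72 changed transcripts in leaf, 42.4% of changes of 1 and 84.9% of changes of 2 were recovered, and with 73 in fruit 35.1% and 79%. For circRNA with 22 changed in leaf the shares were 6.25% and 54%, and with 48 in fruit 6.87% and 58.3%. False calls made up 5.65% of the mRNA calls in leaf and 5.81% in fruit, 7.66% and 5.26% of the lncRNA calls, and 10.9% and 12.8% of the circRNA calls, so the circRNA error rate was above the nominal one.

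Alternatives fixed before the data were examined were another pseudocount, no filter on low values, rescaling of the libraries, a replicate block within tissue, leaving out each library in turn, the 6 compared libraries alone, a minimum log2 change of 1 and, outside circRNA, a robust variance without trend. Alternatives chosen after seeing the data left out a run of identifiers or a region of chromosome 8, entered that region as a single summed feature, summed the models of a locus, kept only features above 0 in all 12 libraries, or used voom on junction reads recovered from the circRNA values. FPKM carry no counts, so the sequencing depth behind the mRNA and lncRNA values is unknown. The recovered junction reads ranged from 13633 to 34763 per library.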

Results

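Total RNA was profiled in lychee leaves and fruits 24 h after inoculation with Peronophythora litchii or a water mock, with 3 libraries in each of 4 groups. Between 17171 and 18430 mRNA features per library reached an FPKM of 0.5, and between 635 and 784 circRNAs were detected. The first principal component of the mRNA values held 76.3% of the variance and separated fruit from leaf. The second held 4.38% and separated inoculated from mock leaf, and the third held 3.7% and separated inoculated from mock fruit. No pair of libraries within a group held the same values, with Pearson correlations across genes between 0.941 and 0.964.

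In leaf, 1351 of 20383 mRNAs rose and 1190 fell with inoculation (limma, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: the median absolute log2 change of the called mRNAs was 0.45, and 163 rises and 63 falls reached 1. LITCHI031619.m1.gene rose from 0.985 ± 0.356 FPKM in mock leaf to 65.0 ± 5.66 in inoculated leaf (SD, n = 3), a log2 change of 5.07 ± 0.14 (SE; limma, Benjamini-Hochberg adjusted p = 8.62e-09). Its values in fruit were 0.83 ± 0.272 in mock and 1.01 ± 0.043 in inoculated libraries (SD, n = 3). LITCHI008367.m3.gene was listed at 0 in each mock leaf library and at 80.8, 72.5 and 3.96 FPKM in the inoculated ones (limma, Benjamini-Hochberg adjusted p = 0.00291). In fruit it had 81.2 ± 5.36 FPKM in mock and 138 ± 17.1 in inoculated libraries (SD, n = 3). Another model of its locus stood at 42.4 ± 1.08 FPKM in mock leaf and at 1.12, 3.36 and 45.3 in the inoculated libraries. The greatest falls were of LITCHI031068.m1.gene and LITCHI031115.m1.gene, both listed at 0 in all inoculated leaf libraries. In mock leaf the former had 20.2, 5.27 and 38.0 FPKM and the latter 20.2, 5.21 and 37.9 (limma, Benjamini-Hochberg adjusted p = 0.000335 and 0.000358). Another model of the latter's locus rose, from 0 in each mock library to 12.6, 24.2 and 0.716 FPKM (limma, Benjamini-Hochberg adjusted p = 0.0218). Both named models and this other model lie in a run of consecutive identifiers, in which the commonest level was 20.5, 5.22 and 38.1 FPKM in these 3 mock libraries. In inoculated leaf 1 and 2 it was 11.1 and 24.0 FPKM. None was found in inoculated leaf 3, where a level under 3 FPKM would have been missed. Where this level was found, these models stood near it or at 0, so their falls and rise cannot be told apart from it. Over all 20383 tested mRNAs, the 3 inoculated and 3 mock leaf libraries did not overlap for 5992, where chance gives 10%. Fitted to the 6 leaf libraries alone, the count was 1446, and LITCHI008367.m3.gene had an adjusted p of 0.0614, the highest over its alternatives, which began at 1.31e-09.

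In fruit, 944 mRNAs rose and 1498 fell (limma, Benjamini-Hochberg adjusted p under 0.05). Rescaling the libraries by their median ratio turned this balance, with 1340 rises and 1010 falls, so the excess of falls depends on the scaling. Rises of at least 1 on the log2 scale numbered 94 and falls 87. Litchi_chinensis_newGene_1033 was listed at 0 in all mock fruit and all leaf libraries, and at 212, 17.98 and 200 FPKM in inoculated fruit (limma, Benjamini-Hochberg adjusted p = 0.000227). All its spread lay in inoculated fruit, and the fit shared that spread with groups at 0, so this p-value is likely too small. Its highest adjusted p over the alternatives was 0.0176 (limma, Benjamini-Hochberg). LITCHI024583.m1.gene was listed at 0 in each mock fruit library and at 12.9, 12.1 and 14.2 FPKM in inoculated fruit (limma, Benjamini-Hochberg adjusted p = 0.00047). Another model of that locus fell from 24.0 ± 2.06 to 11.1 ± 2.38 FPKM (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.00281). LITCHI026407.m1.gene had 10.7 ± 1.22 FPKM in mock fruit and 0, 0.584 and 1.05 in inoculated fruit, with a log2 change of -2.98 ± 0.58 (SE; limma, Benjamini-Hochberg adjusted p = 0.00742). LITCHI020736.m1.gene fell from 13.9 ± 1.65 to 1.73 ± 0.478 FPKM (SD, n = 3), with a log2 change of -2.46 ± 0.65 (SE; limma, Benjamini-Hochberg adjusted p = 0.035). Another model of each of these 2 loci rose, from 0.25 ± 0.0746 to 10.7 ± 0.878 FPKM and from 0.497 ± 0.217 to 7.33 ± 0.848 FPKM (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.00225 and 0.0134). The call of LITCHI020736.m1.gene was lost under 8 alternatives, with adjusted p up to 0.106, and kept under 12. Among the losses were the fits without any 1 of the 6 fruit libraries.

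The responses of leaf and fruit shared more called mRNAs than independent lists would. In both tissues 234 mRNAs rose, where independence gives 62.6, and 182 fell, where it gives 87.5 (Fisher's exact test, Benjamini-Hochberg adjusted p = 2.04e-74 and 9.42e-22 over 4 classes; genes are not independent). A further 165 rose in leaf and fell in fruit, where independence gives 99.3, and 65 fell in leaf and rose in fruit, where it gives 55.1 (Fisher's exact test, Benjamini-Hochberg adjusted p = 6.21e-11 and 0.155). Both lists come from a single fit with a shared variance estimate per mRNA, so independence is not a strict null. A class of opposite direction was above it too. After rescaling, 322 rose and 119 fell in both. Across all 20383 mRNAs, which are not independent replicates, the log2 changes in leaf and fruit had a Pearson correlation of 0.04.

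**Figure D1:**
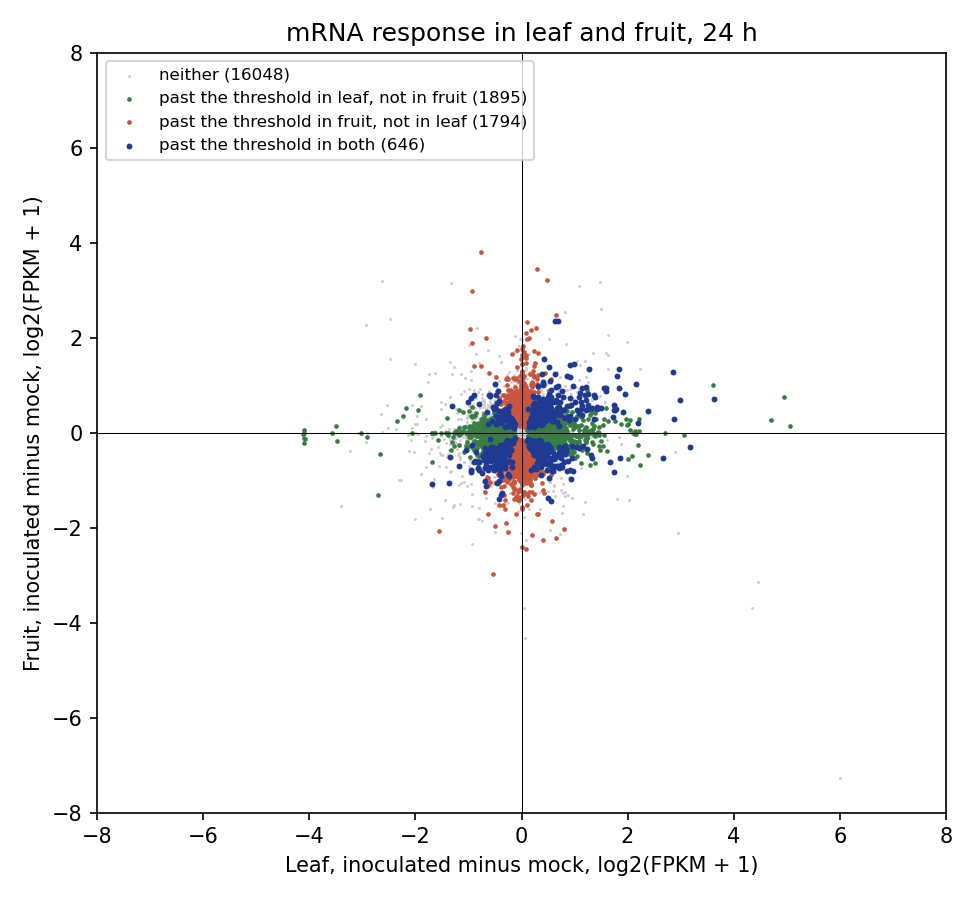
Difference of group means on the log2(FPKM + 1) scale between inoculated and mock libraries, in leaf on the horizontal axis and in fruit on the vertical axis, for 20383 mRNAs, each a point coloured by the tissue in which it passed the threshold. Most called mRNAs lie near an axis, and the Pearson correlation across mRNAs is 0.04.

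The response itself differed between the tissues for 2447 mRNAs. It was higher in fruit for 940, of which 486 fell in leaf and 413 rose in fruit, and lower in fruit for 1507, of which 770 rose in leaf and 745 fell in fruit (limma, Benjamini-Hochberg adjusted p under 0.05). Rescaling gave 1132 and 1289. Litchi_chinensis_newGene_1033 and LITCHI024583.m1.gene had the greatest excess in fruit, by 6.55 ± 1.01 and 4.56 ± 0.65 on the log2 scale (SE; limma, Benjamini-Hochberg adjusted p = 0.00223 and 0.00145). LITCHI031619.m1.gene had a fruit response minus leaf response of -4.92 ± 0.20 (SE; limma, Benjamini-Hochberg adjusted p = 6.4e-07). LITCHI018291.m1.gene had -4.42 ± 0.18 (SE; limma, Benjamini-Hochberg adjusted p = 6.4e-07): it rose from 0.667 ± 0.244 to 42.0 ± 1.89 FPKM in leaf and had 3.95 ± 0.539 and 5.0 ± 0.683 FPKM in mock and inoculated fruit (SD, n = 3).

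Between the mock tissues, 8497 mRNAs were higher in fruit and 5490 in leaf (limma, Benjamini-Hochberg adjusted p under 0.05). Rescaling gave 7042 and 6888, since it moved the median log2 difference by -0.169. LITCHI029733.m1.gene had 719 ± 29.95 FPKM in mock fruit and 1.79 ± 0.195 in mock leaf, 402-fold higher (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 2.83e-13). LITCHI023680.m1.gene had 1388, 2733 and 2813 FPKM in mock fruit and 1014, 0 and 0 in mock leaf, and its adjusted p of 0.0465 in limma with Benjamini-Hochberg adjustment was lost under 13 of 19 alternatives, up to 0.645. LITCHI021094.m1.gene and LITCHI024428.m1.gene were listed at 0 in all fruit libraries and had 125 ± 12.3 and 102 ± 9.14 FPKM in mock leaf, against 29.1 ± 1.46 and 30.7 ± 2.47 in inoculated leaf (SD, n = 3).

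Few lncRNAs passed the threshold. In leaf, 1 of 842 rose and 14 fell, and these 15 came from 14 loci, and in fruit 1 rose and 1 fell (limma, Benjamini-Hochberg adjusted p under 0.05; 108 and 61 at an unadjusted p under 0.05). MSTRG.5885.21 rose in leaf from 7.75 ± 4.06 to 90.2 ± 49.4 FPKM (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.0213). In fruit it had 91.5 ± 35.2 FPKM in mock and 107 ± 76.3 in inoculated libraries (SD, n = 3). MSTRG.26971.1 fell from 28.2 ± 2.02 to 7.86 ± 1.62 FPKM and MSTRG.25120.6 from 5.28 ± 1.19 FPKM to 1.10, 0.729 and 0 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.0184 and 0.00132). In fruit, MSTRG.18142.1 had 0.967 ± 0.138 FPKM in inoculated libraries and 0.0831, 0 and 0 in mock, and MSTRG.22315.2 fell from 1.49 ± 0.138 to 0.464 ± 0.104 FPKM (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.00123 and 0.0116). The response differed between tissues for 5 lncRNAs, each higher in fruit. Of these, MSTRG.25120.6 and MSTRG.25120.5 differed by 2.01 ± 0.34 and 1.58 ± 0.26 on the log2 scale, both being listed at 0 in all fruit libraries (SE; limma, Benjamini-Hochberg adjusted p = 0.0221 for both). These calls were lost under 11 of 17 and 12 of 17 alternatives, with adjusted p from 0.0137 up to 0.34 and 0.278, that of MSTRG.22315.2 under 7 of 18 (0.0125 to 0.395), that of MSTRG.5885.21 under 6 of 18 (0.011 to 0.0981), and those of MSTRG.26971.1, MSTRG.25120.6 in leaf and MSTRG.18142.1 under 4, 3 and 2 of 18 (up to 0.101, 0.0981 and 0.132). The count in leaf was 25 without inoculated leaf 3, 9 without mock leaf 2 or the filter on low values, and 1 with pseudocount 0.1. With the 6 libraries of a tissue alone it was 0 in leaf and in fruit, as it was with the replicate block within tissue. Rescaling gave 5 rises and 12 falls in leaf and 1 rise and 2 falls in fruit.

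circRNAs, formed by back-splicing, were called 8 times in leaf, with 4 rises and 4 falls, and 17 times in fruit, with 13 rises and 4 falls (limma, Benjamini-Hochberg adjusted p under 0.05, of 720 tested). Of the 17 in fruit, 7 lay within 1404 bases of chromosome 8, and without that region 8 passed, with 5 rises and 3 falls. The junction on chromosome 13 from 12638598 to 12653782 rose in both tissues, from 2.28 ± 0.784 to 25.2 ± 4.07 in leaf and from 9.14 ± 1.64 to 41.2 ± 10.2 in fruit (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.000167 and 0.00191). The junction on chromosome 1 from 13840451 to 13914010 rose in leaf to 1.05 ± 0.172 from 0, 0.17 and 0, on 36 and 2 reads (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.00327). In fruit it had 20.9 ± 4.08 in mock and 37.5 ± 2.31 in inoculated libraries (SD, n = 3). Falls in leaf were called for chromosome 1 from 48401093 to 48412499, on 27 reads in mock and 0 in inoculated libraries, and for chromosome 6 from 28756760 to 28791576, on 17 and 0 reads (limma, Benjamini-Hochberg adjusted p = 0.00826 and 0.0451). The call on chromosome 6 was lost under 15 of 19 alternatives, up to an adjusted p of 0.847, and those on chromosome 1 under 4 and 3 of 19, both up to 0.65.

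In fruit, the junction on chromosome 5 from 30814962 to 30819460 had values of 240, 283 and 180 in inoculated libraries, on 7969 reads in sum, and 0 in the other 9 libraries, at least 887-fold higher than mock with a floor of 3 reads per library (limma, Benjamini-Hochberg adjusted p = 1.45e-09). The junction on chromosome 8 from 21413519 to 21413766 had 7.64 ± 0.946 (SD, n = 3) in inoculated fruit and 0 in the other groups, at least 28.9-fold higher (limma, Benjamini-Hochberg adjusted p = 1.32e-06). It lies in the region of 1404 bases, where 202 circRNAs were listed and the summed value was 342 ± 26.3 in inoculated and 192 ± 24.4 in mock fruit, 1.78-fold higher (SD, n = 3; exact permutation p = 0.1, the smallest possible). A junction with the same end and a start 36 bases away, at 21413555, picked after its values were seen, had 16.6 ± 1.51 in inoculated and 10.7 ± 2.9 in mock fruit (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.433). On chromosome 11, the junction from 23219173 to 23228747 had 5.03 ± 1.19 (SD, n = 3) in mock fruit and 0 in inoculated fruit, at least 18.6-fold lower, and that from 267843 to 272581 had 15 reads in mock fruit and 0 in inoculated fruit (limma, Benjamini-Hochberg adjusted p = 6.28e-06 and 0.00191). The call of the latter was lost under 3 of 19 alternatives, up to an adjusted p of 0.168. In leaf the former had 3.37 ± 1.34 in inoculated and 3.68 ± 0.556 in mock libraries (SD, n = 3). With the 6 libraries of a tissue alone, 1 circRNA passed in leaf and 10 in fruit, and in leaf 4 passed without mock leaf 2 and 5 without inoculated leaf 2. With the replicate block within tissue, 1 passed in leaf and 6 in fruit. With voom on recovered reads the chromosome 5 junction in fruit and the chromosome 13 junction in leaf did not pass, at adjusted p of 0.734 and 0.316. Some voom weights were extreme, but whether those of these junctions were is not shown, so the cause of these losses was not tested.

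**Figure D2:**
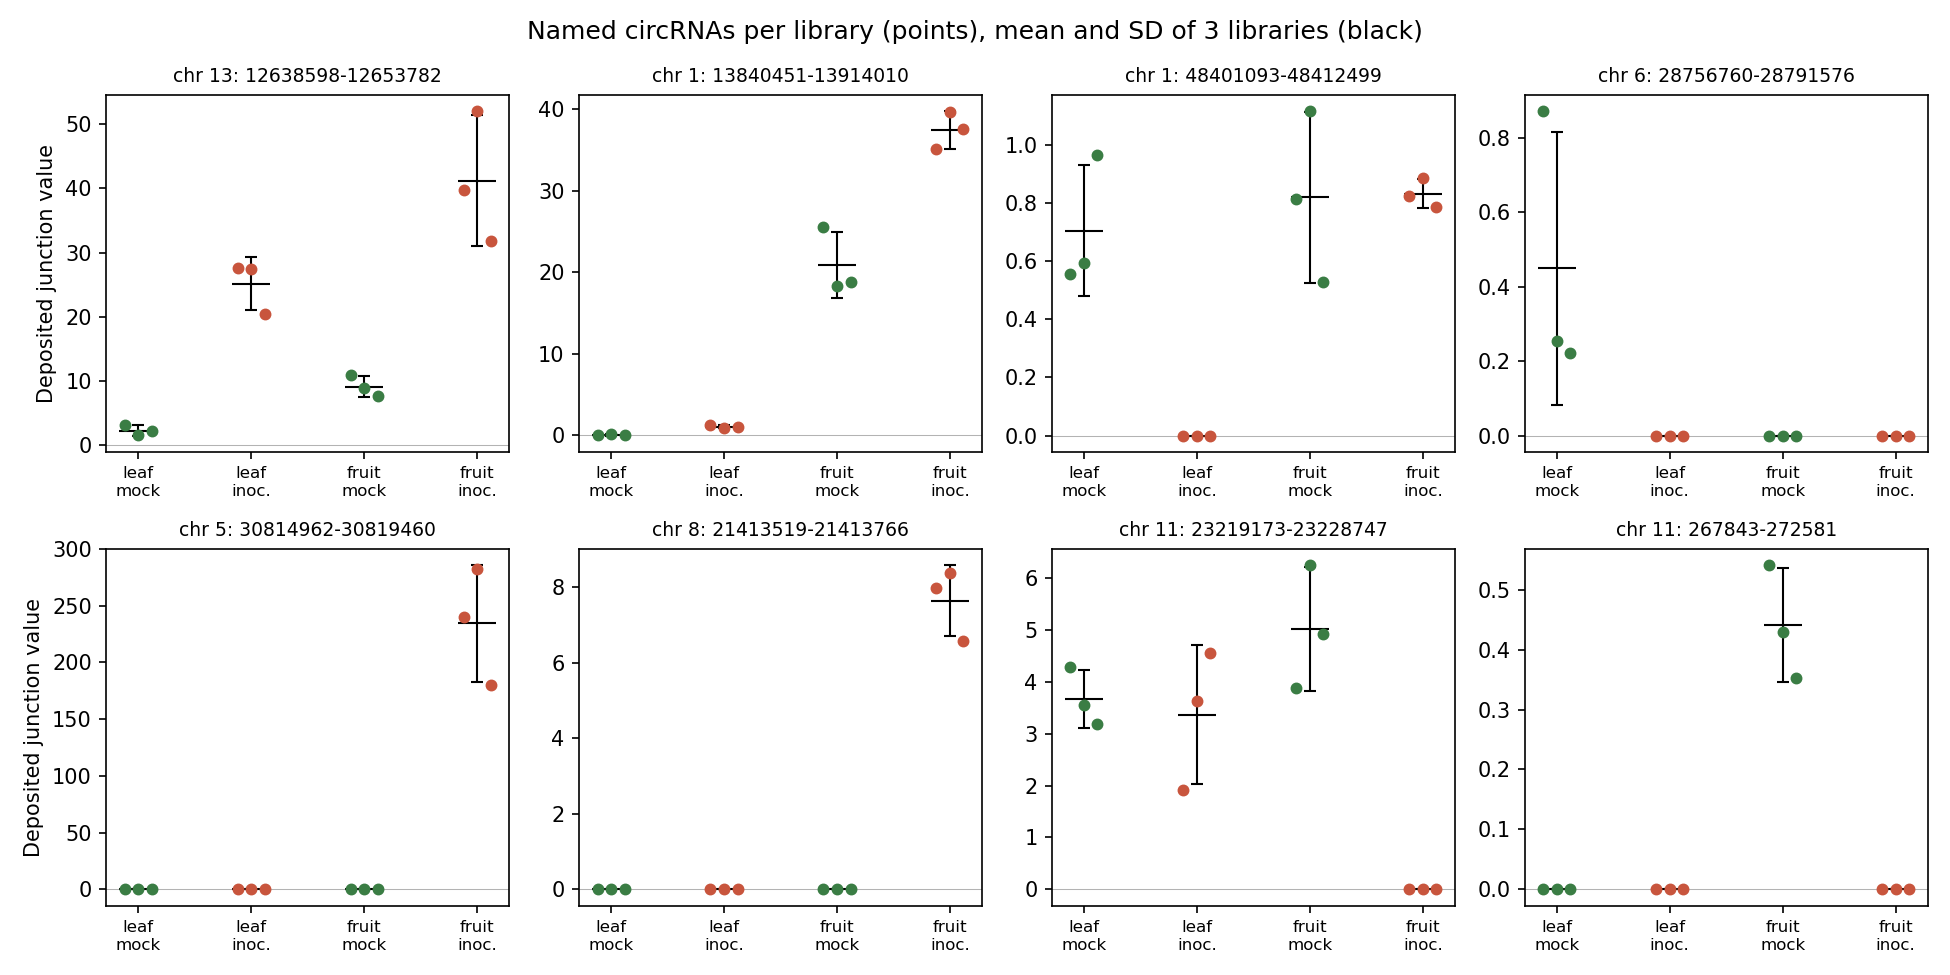
Deposited junction values of the 8 named circRNAs in each library (points: mock green, inoculated red), with the mean and SD of 3 libraries in black, on linear axes that differ between panels. The junction on chromosome 5 is at 240, 283 and 180 in inoculated fruit and at 0 in the other 9 libraries.

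**Figure D3:**
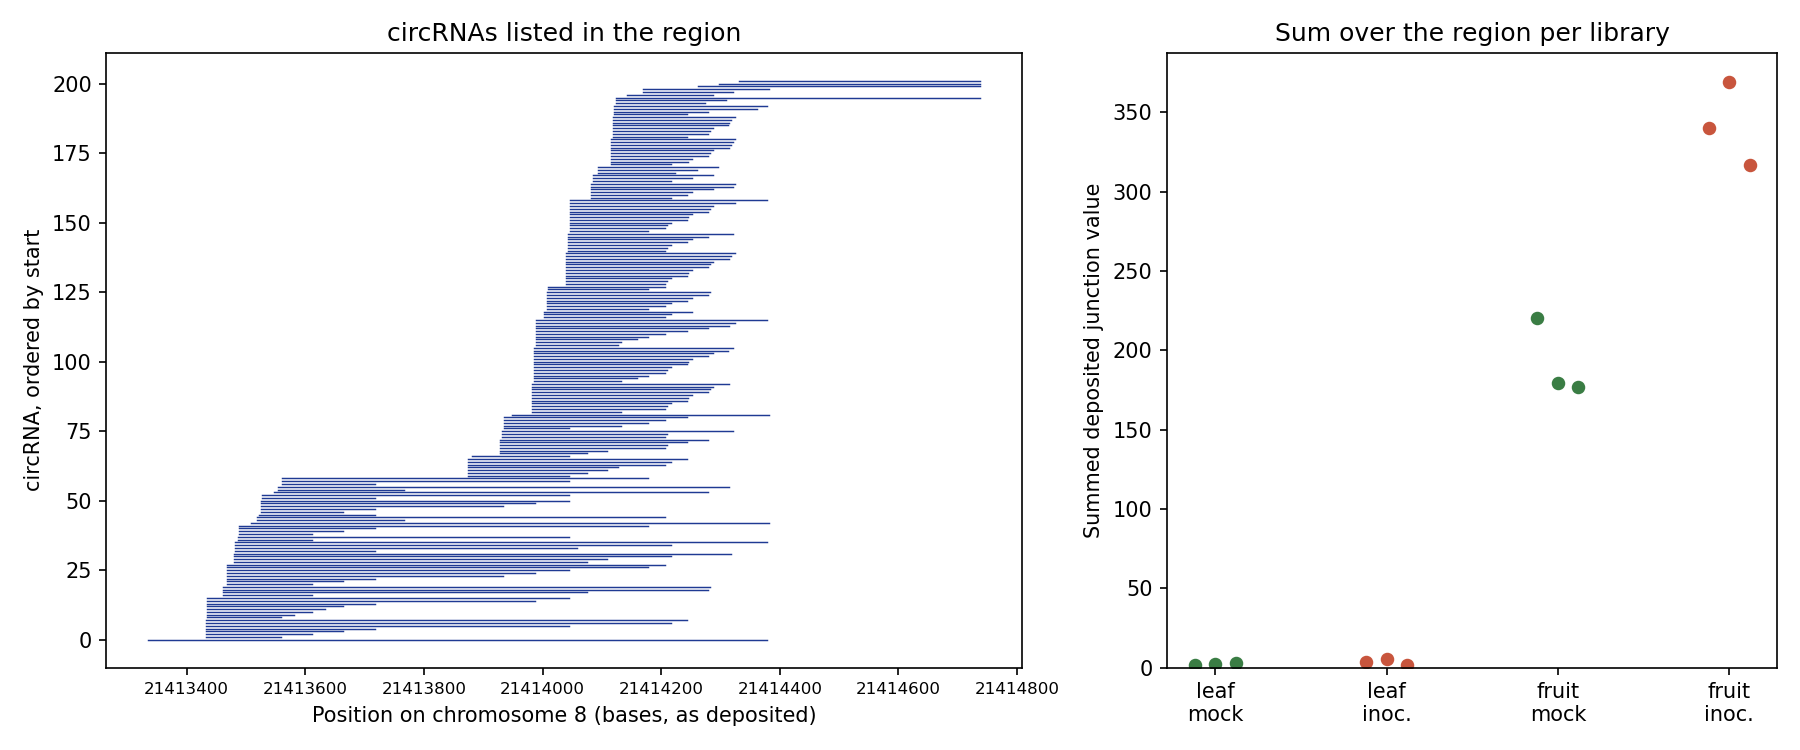
Left, the 202 circRNAs listed on chromosome 8 between 21413335 and 21414738, each a line from its start to its end. Right, their summed junction value per library (mock green, inoculated red): 317 to 369 in inoculated fruit, 177 to 220 in mock fruit and at most 5.5 in leaf.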

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

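The tests of the 3 patterns in this part were chosen after the results were seen. The counts over other splits were chosen before, except that the one with list sizes held was added later, before its outcome was seen. In the planned tests of the difference itself, which left out circRNAs, a response that differed between leaf and fruit was found for 2447 mRNAs and 5 lncRNAs. The named mRNAs among them were Litchi_chinensis_newGene_1033 at 6.55, LITCHI024583.m1.gene at 4.56, LITCHI031619.m1.gene at -4.92 and LITCHI018291.m1.gene at -4.42, as fruit minus leaf response on the log2 scale. The named lncRNAs were MSTRG.25120.6 at 2.01 and MSTRG.25120.5 at 1.58. Both are listed at 0 in all fruit libraries, and Litchi_chinensis_newGene_1033 in all leaf libraries, so for these 3 the difference restates the change in the other tissue. The circRNA fit gave a difference for the junctions on chromosome 5 at 10.60, chromosome 8 at 5.71 and chromosome 11 from 23219173 at -4.91 (limma, Benjamini-Hochberg adjusted p = 5.83e-08, 4.67e-05 and 3e-04). Smaller ones were from 267843 on chromosome 11 at -1.98 and from 48401093 on chromosome 1 at 2.56 (limma, adjusted p = 0.0377 and 0.0435). The other named circRNAs did not pass. Those on chromosome 5 and 8 and from 267843 are at 0 in all leaf libraries.

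For the difference of mRNA responses, 1 of 100 splits, the real one, gave 2447 mRNAs or more, and the highest other split gave 540. This share is under the 0.05 set against chance. The other splits mix inoculated and mock libraries, so the count does not show how many mRNAs would differ if both tissues responded alike. For the overlap of the tissues 1 of 100 splits, the real one, gave 416 mRNAs called in the same direction and the highest other gave 2, which decides nothing, since the other splits called too few mRNAs. With the list sizes held at the 2541 and 2442 mRNAs of smallest p, the real split shared 416 in the same direction. The highest other split shared 259, so 1 of 100 splits, the real one, gave as many. The lists of the other splits hold mostly mRNAs not past the threshold. This count therefore does not show whether the 416 exceed what unrelated responses of the tissues would share. For the difference of lncRNA responses 7 of 100 splits gave 5 or more, up to 9, so chance cannot be excluded. The 10 splits of 6 libraries are too few for a share under 0.05. Of these, 1 gave as many mRNAs in leaf (2541, highest other 8), in fruit (2442, highest other 12) and between mock tissues (13987, highest other 2). For lncRNA, 1 split gave as many in leaf (15, highest other 4) and 3 in fruit (2, highest other 4). For circRNA, 3 splits gave as many in leaf (8, highest other 8) and 1 in fruit (17, highest other 8).

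A run of mRNA identifiers from 30909 to 31200 held 9 of the 20 greatest falls in inoculated leaf. A common level was looked for only where the 10th percentile of 40 consecutive non-zero features exceeded 3 FPKM, so lower levels are missed. The commonest level in the run was 20.5, 5.22 and 38.1 FPKM in the mock leaf libraries and 11.1 and 24.0 in inoculated leaf 1 and 2. No such level was found in inoculated leaf 3 or in fruit. The tables argue against a response to inoculation as the whole source, since this level ranged 7.29-fold over the mock libraries, where 99% of other features of that level ranged less than 2.11-fold. Near-identical copies would have alike levels in fruit, where the 90th percentile of mock FPKM in the run was 132 times the 10th. Since the level was not found in fruit, this value cannot show whether reads shared between copies made it in leaf. An amount added per library may be the source but cannot be told apart. The lowest share of non-zero features at or above 95% of the amount was 82.74%, short of the 90% set for this test. Outside the run, the highest such share in a leaf library with the level was 34.04%.

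Some models of a locus were called in opposite directions, 14 pairs in leaf and 9 in fruit, among them 2 of the 20 greatest changes in leaf and 6 of 20 in fruit. Their models were 1.06% of the called mRNAs in leaf and 0.696% in fruit. Reads assigned to another model of the same locus may be a source. In the tissue that did not make the call, the deviations of such models had a median correlation of -0.67 over 22 pairs, of which 15 were negative. Of 1000 draws of random pairs, 95% gave -0.30 to 0.31. At the threshold the real split of the fruit libraries held 9 such pairs and the other 9 splits at most 2. With the 2442 mRNAs of smallest p taken in each split, the real split held 9 and the other splits 63 to 97. Those splits mix inoculated and mock libraries, so this count does not show what arises without inoculation. The bound set for the second count, that no other split gives as many, was crossed, and it was judged wrong only after the count was seen: the other splits called at most 12 mRNAs, which fixes the first count and fills the lists of the second mostly with library noise. That inoculation changes which model is transcribed at these loci stays open.

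On chromosome 8, 202 of the 4682 circRNAs lay within 1404 bases, and the next largest cluster held 36. Reads crossing a short tandem repeat may be the source of their number, since junction coordinates 36 bases apart occurred 5.75 times as often as the median distance. A rise of the region's junction values in inoculated fruit stays open. The sum was 342 ± 26.3 against 192 ± 24.4 in mock (SD, n = 3), and as 1 summed feature in the fit of 12 libraries it differed by 0.84 on the log2 scale (95% interval 0.14 to 1.53; limma, unadjusted p = 0.0222, Benjamini-Hochberg adjusted p = 0.562 over 615 features).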

How the results depend on the processing

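The alternatives that omitted a run or region, summed models, required values above 0 in all 12 libraries or used voom were chosen after seeing the data. Of 205 values of the main comparisons under alternatives, 159 stayed within 1.5 times and 46 did not. No named change reversed in 580 values, and 94 lost the threshold. The named changes were picked as the greatest with non-overlapping groups in these same libraries, so a reversal was unlikely from the start. A minimum log2 change of 1 left 226 mRNAs in leaf, 181 in fruit, 437 for the difference, 5651 between mock tissues and 7 in the overlap, and 8 lncRNAs in leaf and 0 in fruit, by construction. The 6 compared libraries alone gave 1446 mRNAs in leaf, 0 lncRNAs in leaf and in fruit, and 1 and 10 circRNAs. That fit has fewer samples and leaves the other tissue out of the variance, where many features are at 0. Which of these lowered the counts was not tested. Pseudocount 0.1 gave 1 lncRNA in leaf, 1 in fruit and 0 for the difference, and no filter on low values gave 9, 1 and 0; the cause was not tested. Without the chromosome 8 region, or with it as 1 summed feature (also chosen after seeing the data), 8 circRNAs passed in fruit, with fewer tested. With voom 29 passed in fruit, but the named junction on chromosome 5 had an adjusted p of 0.734 (from 3.29e-18 over its alternatives) and that on chromosome 13 in leaf 0.316 (from 1.36e-09). Weights reached 5.23e+07 against a median of 0.619, so voom is unreliable where weights are that extreme. Whether those of these named junctions were is not shown. Same-numbered deviations correlated at 0.05, -0.23 and -0.16 in leaf and 0.06, 0.02 and 0.04 in fruit. Each fruit library and leaf 1 correlated best with its own number, leaf 2 and 3 did not. These values do not settle whether replicate numbers pair the samples. The replicate block gave 1824 mRNAs in leaf, 1672 in fruit, 1610 for the difference, 0 lncRNAs in each comparison, and 1 and 6 circRNAs. Leaving out each library gave 1696 to 2449 mRNAs in leaf, 1651 to 2505 in fruit, 1798 to 2275 for the difference, 13176 to 14056 between mock tissues and 301 to 401 in the overlap. The lncRNA ranges were 9 to 25 in leaf (25 without inoculated leaf 3, 9 without mock leaf 2), 1 to 4 in fruit (4 without mock fruit 1 or 3, 1 without inoculated fruit 1 or 2 or mock fruit 2) and 0 to 7 for the difference (0 without inoculated leaf 2, mock leaf 2, inoculated fruit 2 or 3, or mock fruit 2; 1 to 3 without inoculated leaf 1, mock leaf 1, inoculated fruit 1, mock fruit 1 or 3). The circRNA ranges were 4 to 10 in leaf (4 without mock leaf 2, 5 without inoculated leaf 2) and 12 to 21 in fruit. The alternatives planned for gene lists were not run, since the identifiers are not paired with names.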

Other observations

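Inoculated leaf profiles lay closer to fruit than mock leaf profiles did; these values were computed after seeing the data. The correlation with the mean mock fruit profile, across mRNAs outside the run of identifiers, was 0.809 to 0.811 in inoculated leaf and 0.780 to 0.786 in mock leaf (exact permutation p = 0.1, the smallest possible with n = 3 in each group; 0.17 after Benjamini-Hochberg adjustment over 29 comparisons). With each mock leaf library in turn kept out of the leaf reference, inoculated leaf lay 11.2% to 12.2% of the way from leaf to fruit, over mRNAs that differed by at least 1 on the log2 scale, and the library kept out lay at 1.84% to 3.5%. Among mRNAs at least 2 higher in leaf than in fruit, the median change with inoculation, against the library kept out, was -0.21 to -0.22, and among those at least 2 higher in fruit it was 0.17 to 0.22. The correlation with the mean mock leaf profile was 0.770 to 0.775 in inoculated fruit and 0.780 to 0.784 in mock fruit, so by this measure inoculated fruit lay farther from leaf (exact permutation p = 0.1, the smallest possible with n = 3 in each group; 0.17 after Benjamini-Hochberg adjustment). On the path measure inoculated fruit lay 2.11% to 3.71% of the way to leaf, and the mock fruit library kept out at 2.71% to 3.56%.

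The summed circRNA value was 2670 ± 111 in inoculated fruit and 2140 ± 59.2 in mock fruit (SD, n = 3; exact permutation p = 0.1). Without the chromosome 8 region and the chromosome 5 junction it was 2094 ± 48.1 and 1948 ± 42.8. Of the 4682 circRNAs, 3521 were listed in a single library and 47 in all 12.

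The 22 transcripts of the lncRNA locus MSTRG.5884 held 48.7% ± 0.196 of all lncRNA FPKM in inoculated leaf, 38.2% ± 6.42 in mock leaf, 68.0% ± 2.75 in inoculated fruit and 64.7% ± 4.60 in mock fruit (SD, n = 3). Genes given as new were called less often than the other models, at 6.4% against 12.6% in leaf and 6.58% against 12.1% in fruit (Fisher's exact test, p = 3.77e-06 and 3.19e-05; genes are not independent). Their FPKM levels were not matched, and the scale understates changes of low features, so the source of this difference was not tested.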
